A study of Mus musculus with 6 samples.

How the data were processed

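Genomic DNA of whole bone marrow and ear from 3 mice, 6 samples in all, had been captured with a 50 Mb mouse exon kit and sequenced to a stated mean depth of 100 reads, per the labels' protocols. The submitters' processing notes name FastQC, Bowtie2 and SAMtools and the builds GRCm38 and mm9, without saying which step used which. Of 19965 coding sites in the ear lists whose gene has a RefSeq entry, 99.3% lay inside the span of that gene in GRCm38.p6, so coordinates are given as positions in GRCm38. Of 7510 gene names with a coding call, 7367 were found as a RefSeq symbol or synonym.

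The deposited files were of 3 kinds. A list of all variants of each sample had been made with SAMtools and annotated with SnpEff, per the file headers, and holds in its information field the depth, the mapping quality and the read count per allele and strand. The lowest depth in these lists was 11 reads. The authors' VarScan2 lists give for each call the deposited read counts per allele in marrow and ear, the variant fraction in percent, and a somatic p-value. The authors' Strelka lists of passed calls give a quality per call and no read count. Each somatic list compares marrow with ear of 1 animal. VarScan2 calls are marked somatic or LOH (loss of heterozygosity), and those marked somatic were taken as somatic calls, while LOH calls were counted apart. The filters of both callers are not given in the sources used here. To check which column held which tissue, VarScan2 read counts were compared with the all-variant list of each sample: at single nucleotide sites in both, the assigned marrow column was the closer one in 440 of 441 sites of animal 54, 977 of 979 of animal 108 and 263 of 263 of animal 136. The assigned ear column was the closer one in 273 of 277, 325 of 341 and 65 of 71 sites.

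From these files, each site was reduced to its SnpEff annotation of highest impact, protein-altering meaning HIGH or MODERATE impact. A site was counted as coding when any of its annotations had an impact of LOW or above, which takes in splice regions. Variant fractions are reads of the variant allele over reads of both alleles. A call matched between lists when chromosome, position and alleles were the same. Shares have Clopper-Pearson intervals and numbers of calls have exact Poisson intervals, at a level of 95%. These cover counting error only, since reads without molecular identifiers are not independent molecules, and a list gives no depth at sites that were not called. Neighbouring calls in a list can lie on the same reads. Intervals and tests that count calls or sites treat them as independent all the same. Depths at coding sites, with medians from 52 to 117.5 reads, mean that a variant fraction at a single site is known to within about its printed interval and not better. Mean and SD are over the 3 animals.

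Tests were Fisher's exact test on reads or calls, the exact paired sign-flip permutation test, the chi-square permutation test with fixed margins and 100000 resamples, random gene draws (10000) and, for the sites called in all 6 samples, the Cochran-Mantel-Haenszel test with animal as stratum and a continuity correction, which is a chi-square approximation; an exact conditional test over the same strata was added. Adjusted p-values are Benjamini-Hochberg values and the threshold was 0.05. Sites needed at least 10 reads of both alleles together in each sample tested. The gene list test used as background the 7506 genes with at least 1 coding call in any list, the somatic lists included, so that 2432 of them are genes with the call that is tested. Marrow and ear with the same animal number come from the same animal, per the labels, so animal was the pair or stratum in each test of tissue. In a check over the sites called in all 6 samples, the deviations of marrow and ear fractions from their tissue means were correlated. The correlations were 0.153, 0.196 and 0.111 (across sites, which are not independent) in animals 54, 108 and 136. No marrow correlated above 0 with the ear of another animal. Deviations from a mean of 3 animals sum to 0, so positive own pairs push the others below 0, which adds no separate support.

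The per-site tests were checked on simulated reads at the real depths, with 200 sites shifted. A shift of 0.4 in variant fraction was recovered by the Fisher step at 62.5%, 49.0% and 50.0% of changed sites in animals 54, 108 and 136 (31835, 48977 and 11026 sites). The Cochran-Mantel-Haenszel step recovered 99.5% of them over 4444 sites, and 65.5% of shifts of 0.2. The simulated reads varied by binomial sampling alone, and only sites of intermediate fraction were shifted. In the Cochran-Mantel-Haenszel step each shifted site moved by the same amount in all animals. Recovery at real sites may be lower than under these settings.

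The lists, tests, most alternatives and the rule for named genes were set before the data were examined. The rule takes Srsf2, every gene of the lists fixed by symbol with a protein-altering somatic call, up to 10 protein-altering calls per animal found by both callers, genes with such calls by both callers in more than 1 animal, and the 10 genes with the smallest p in the test over 3 animals whose fraction moved the same way in each. Families defined by name prefix were given as counts. Alternatives were a higher depth, stricter caller thresholds, leaving out positions in any ear list, the other caller, other impact classes and backgrounds, single nucleotide sites or indels alone, no pairing, and leaving out each animal. The lists hold no variant quality, and a mapping quality of at least 30 was used in its place. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, numba 0.67.0 and biopython 1.88, and plots used matplotlib 3.10.9.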

Results

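Exome capture sequencing was carried out on genomic DNA of whole bone marrow and of matched ear tissue from 3 mice carrying the P95H change of Srsf2, a splicing factor of the SR protein family that is mutated in human myeloid neoplasms. The mice, animals 54 and 108 (males) and 136 (female), had been given tamoxifen and were sampled 50 to 60 weeks later, when they had become moribund. The ear served as the germline reference of each animal, so that a variant found in marrow and not in ear is a candidate for one acquired in blood cells. The sample labels give all 3 animals the R26-CreERT2 driver, whereas the design text gives 1 of them an hScl-CreERT driver, and the driver was therefore not used in any comparison. The lists of all variants held 43259 sites in marrow and 67945 in ear of animal 54, 79759 and 67274 in animal 108, and 26602 and 24915 in animal 136. The median depth at sites with a coding effect was 82 reads in marrow and 117.5 in ear of animal 54, 96 and 94 in animal 108, and 77 and 52 in animal 136. Reads of both alleles summed over sites ranged from 1603891 in ear of animal 136 to 5952217 in ear of animal 54. Animals 54, 108 and 136 are the replicates, with 3 samples of each tissue.

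The Srsf2 change named in the labels was present in both tissues of all 3 animals. It appeared as 2 adjacent base changes in exon 1 of 3 of Srsf2 (ENSMUSG00000034120, chromosome 11, 116849897 to 116853675 in GRCm38.p6), at positions 116852646 (c.284C>A) and 116852645 (c.285G>T). Annotated one at a time these read as P95Q and P95P, and together they give the codon CAT, which is P95H. At the middle base of the codon, the changed base was carried by 23 of 48 reads in marrow of animal 54 (47.9%, 95% Clopper-Pearson interval 33.3 to 62.8) and by 34 of 81 reads in its ear (42.0%, 31.1 to 53.5). In animal 136 the share was 27 of 55 reads in marrow (49.1%, 35.4 to 62.9) and 28 of 45 in ear (62.2%, 46.5 to 76.2). Animal 108 had the lowest marrow share, 11 of 57 reads (19.3%, 10.05 to 31.9), against 25 of 62 reads in ear (40.3%, 28.1 to 53.6). Nearly all reads at this base lay on the forward strand. They numbered 47, 57 and 53 in marrow and 76, 59 and 45 in ear of animals 54, 108 and 136.

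**Figure D1:**
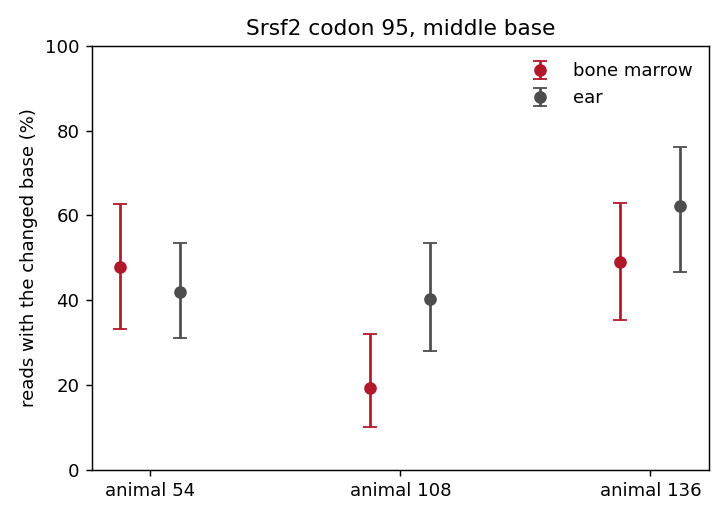
Share of reads with the changed middle base of Srsf2 codon 95 in percent (y axis) in bone marrow and ear of each animal (x axis), with 95% Clopper-Pearson intervals as bars. Marrow of animal 108, at 19.3%, lies below its ear at 40.3%, and the intervals of both tissues overlap widely in animals 54 and 136.

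The marrow share of animal 108 was 21.0 percentage points below its ear, a marrow minus ear difference of -21.0 (95% Wald interval -37.0 to -5.08; two-sided Fisher exact test, p = 0.0164, adjusted p = 0.0493 over the 3 animals). At the adjacent base of the same codon the difference was -18.3 points with an adjusted p of 0.123 by the same exact test, so the call depended on which of the 2 bases was read. In animal 54 the difference was 5.94 points (exact p = 0.583) and in animal 136 it was -13.1 points (exact p = 0.228). Over animals the share was 38.8% ± 16.9 (SD, n = 3) in marrow and 48.2% ± 12.2 (SD, n = 3) in ear, and an exact paired sign-flip permutation test gave p = 0.5, where 0.25 is the smallest value that 3 pairs allow. The mean difference was -9.40 points ± 13.9 (SD, n = 3), and it was -17.1 without animal 54, -3.59 without animal 108 and -7.54 without animal 136. The construct of the targeted allele is not described in the labels, so these shares were not read as shares of recombined cells. Neither base was in any somatic list.

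Marrow did not carry more variant sites than ear in a direction shared by the animals. Marrow had more sites than ear in 2 of the 3 animals, and the mean log2 ratio of marrow to ear was -0.10 ± 0.48 (SD, n = 3; exact paired sign-flip permutation test, two-sided, p = 1). Sites called in one tissue and not in the other numbered 10527 in marrow and 35213 in ear of animal 54, 29781 and 17296 in animal 108, and 14847 and 13160 in animal 136. Their mean log2 ratio was -0.26 ± 1.32 (SD, n = 3; exact paired sign-flip permutation test, p = 1). Leaving out animal 54 turned both ratios positive, to 0.17 for all sites and 0.48 for tissue-private sites. In each animal the tissue with more sites also had the higher median depth at coding sites. In marrow and ear this depth was 82 and 117.5 reads in animal 54, 96 and 94 in animal 108, and 77 and 52 in animal 136. Depth and tissue can therefore not be told apart in these counts.

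Sites shared by marrow and ear were not spread evenly over the genome. Windows of 1 Mb with at least 50 shared single nucleotide sites, a limit chosen after the densities were seen, numbered 127 in animal 54, 201 in animal 108 and 32 in animal 136, and held 77.5%, 81.9% and 54.9% of these sites. On chromosome 6, the segment from 118 to 123 Mb held 558, 568 and 578 sites in animals 54, 108 and 136, and 76.1% of the 654 sites found there in any animal were in all 3. On chromosome 11, the segment from 57 to 63 Mb held 2260 sites in animal 108, 2199 in animal 136 and 17 in animal 54. The 1 Mb window of Srsf2 held 17, 17 and 20 sites in the same order of animals as on chromosome 6.

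**Figure D2:**
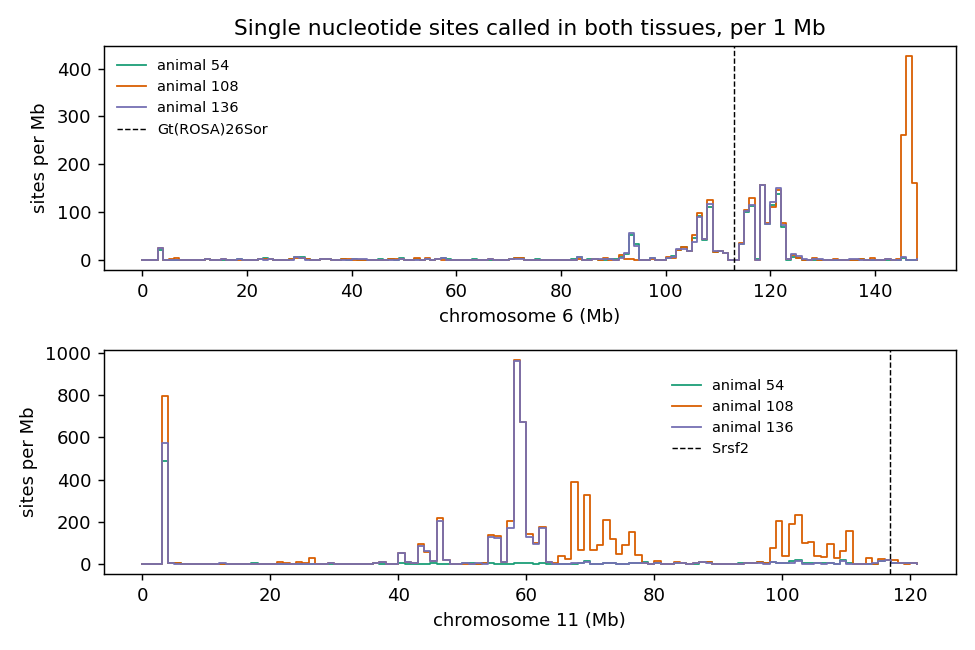
Single nucleotide sites shared by marrow and ear per 1 Mb window (y axis) along chromosomes 6 and 11 (x axis, Mb) in each animal, with the Rosa26 and Srsf2 loci marked. All 3 animals have dense windows between 118 and 123 Mb of chromosome 6, and animals 108 and 136 between 57 and 63 Mb of chromosome 11.

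The lists of somatic calls, in which the authors had compared the marrow of each animal with its own ear, differed strongly between the 2 callers. VarScan2 gave 804 somatic single nucleotide calls in animal 54 (95% Poisson interval 749 to 862), 1425 in animal 108 (1352 to 1501) and 466 in animal 136 (425 to 510), a mean of 898 ± 486 (SD, n = 3). Strelka gave 2854 (2750 to 2961), 1480 (1406 to 1557) and 2078 (1990 to 2169), a mean of 2137 ± 689 (SD, n = 3). VarScan2 listed 224, 258 and 95 somatic indels in animals 54, 108 and 136 (mean 192 ± 86.0, SD, n = 3), and Strelka 79, 52 and 60 (mean 63.7 ± 13.9, SD, n = 3). The order of the animals was not the same in both callers, with animal 108 highest by VarScan2 and lowest by Strelka for single nucleotide calls. Keeping only calls with, in the authors' deposited table, a somatic p under 0.01 in VarScan2 or a quality of at least 30 in Strelka lowered the means of single nucleotide calls to 316 and 688.

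The VarScan2 calls sat at moderate allele fractions in marrow and were often visible in ear. Their median variant fraction in marrow was 28.6% in animal 54, 31.8% in animal 108 and 28.6% in animal 136, with none below 20%, and their median fraction in ear was 11.1%, 9.66% and 6.67%. The filters are not given, so it is not known how far the selection of calls set these fractions. A variant read in ear was lacking in 127 of the 804 calls of animal 54, in 307 of 1425 of animal 108 and in 141 of 466 of animal 136. Strelka calls carried no read counts in the deposited lists. Of the Strelka single nucleotide calls, 17.0%, 13.1% and 8.71% were also in the all-variant list of the same marrow, where their median variant fraction was 13.3%, 12.5% and 12.9%. No Strelka single nucleotide call was in the ear list of its own animal, against 92, 245 and 40 of those of VarScan2.

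**Figure D3:**
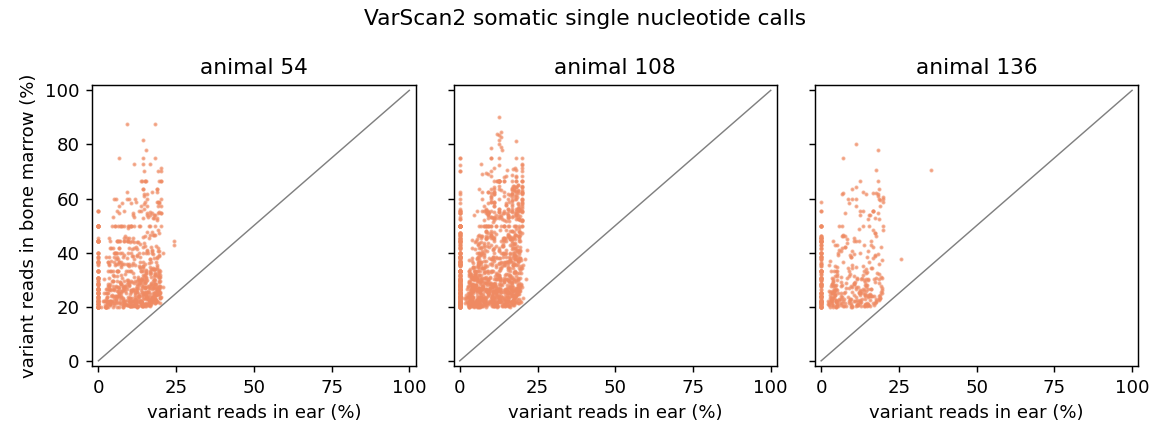
Share of variant reads in bone marrow (y axis, %) against ear (x axis, %) for each VarScan2 somatic single nucleotide call, 1 panel per animal, with the line of equal shares. All calls have at least 20% variant reads in marrow, and most have some variant reads in ear.

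Both callers found 11 calls in common, 6 in animal 54, 4 in animal 108 and 1 in animal 136. These were 0.336% of the 3272 VarScan2 calls (95% Clopper-Pearson interval 0.168 to 0.601) and 0.167% of the 6603 Strelka calls (0.0832 to 0.298). Among them 2 changed a protein. In animal 54 Ivl, which encodes the cornified envelope protein involucrin, had a missense change p.His194Tyr (chromosome 3, position 92572177) in 4 of 13 marrow reads (30.8%, 9.09 to 61.4) and 0 of 39 ear reads. In animal 108 Exoc1, a subunit of the exocyst complex, had p.Ala810Val (chromosome 5, position 76568037) in 4 of 16 marrow reads (25%, 7.27 to 52.4) and 0 of 19 ear reads. The other 9 lay outside coding sequence, and in animal 54 the one in Stam2 lay in its 5' untranslated region (5 of 9 marrow reads and 0 of 27 ear reads). At a depth of at least 20 reads in both tissues 3 of the 11 were left.

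Somatic calls changed proteins more often than the sites shared by both tissues of the same animal. VarScan2 had 155 protein-altering and 97 synonymous calls over the 3 animals, a ratio of 1.60, against 5779 and 8897 among shared sites, a ratio of 0.650 (odds ratio 2.46, two-sided Fisher exact test, p = 2.72e-12). These sums count a site once for each animal that carries it. Neighbouring sites can be inherited or called together, so the exact p-values in this paragraph treat dependent sites as independent and are too small. The odds ratio was 2.69 in animal 54 and 2.72 in animal 108 (exact adjusted p = 2.98e-06 and 3.01e-07 over 6 tests), and 1.32 in animal 136 (exact adjusted p = 0.427). Strelka had 2691 protein-altering and 901 synonymous calls, a ratio of 2.99, and odds ratios of 4.28, 5.32 and 3.54 in animals 54, 108 and 136 (exact adjusted p = 4.54e-125, 1.17e-103 and 4.75e-53). The excess was not particular to marrow, since sites called in ear and not in marrow had a ratio of 2.22 and sites called in marrow and not in ear one of 2.44. Against the ear-private sites, a background chosen after the data were seen, the VarScan2 ratio was lower (odds ratio 0.719, exact p = 0.0185) and the Strelka ratio higher (odds ratio 1.34, exact p = 7.38e-07).

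Of 182 genes in the 7 lists fixed by gene symbol, 29 had a protein-altering somatic call in at least 1 animal, with 38 calls in all. All 38 came from Strelka and none from VarScan2, and 1 of them, in the cohesin gene Smc3 (Q724K, animal 136), was also in the marrow list of all variants, in 4 of 32 reads (12.5%, 95% Clopper-Pearson interval 3.51 to 29.0). In the authors' deposited table the 38 calls had Strelka qualities between 16 and 76, with a median of 23.5, and 15 of them reached 30. None of the 9 lists, including those defined by name prefix, passed the test for an excess of genes with a call over the background of 7506 genes (one-sided Fisher exact test, adjusted p = 1 for each), and 3 of the 7 lists by symbol held more such genes than expected. The lowest unadjusted p of this exact test was 0.179, for the chromatin and DNA methylation regulators. A gene could enter this background through the somatic call itself, so 2 others were added after the data were seen, and none of them accounts for coding length. Against 21900 RefSeq coding genes 6 of the 7 lists by symbol were above expectation and 1 of the 9 passed. The antigen receptor list has 0 members among those genes and could not be tested there. Against the 5551 genes with a coding call in the all-variant lists 3 were above expectation and none passed.

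Among the myeloid neoplasm genes 7 of 19 background members had a call, against 6.16 expected (odds ratio 1.22). The odds ratio was 2.02 with genes having any call as the background, 1.81 with RefSeq coding genes, 0.379 with genes of the all-variant lists, and 2.12 without animal 54, and none of these passed the exact test. Dnmt3a, a DNA methyltransferase often mutated in clonal haematopoiesis, had calls in all 3 animals, H584N and L633Q in animal 54, R362H in animal 108, and A42S and A382T in animal 136. The histone methyltransferase gene Kmt2a had R2010S in animal 108 and E3487D in animal 54. The remaining 5 each had a call in 1 animal, with Gnas (A178E, animal 54), the transcription factor Etv6 (S169C, animal 108), Phf6 (Y124*, a premature stop on chromosome X at 52931704, animal 108), the nucleolar protein gene Npm1 (E254G, animal 136) and the minor spliceosome factor Zrsr2 (L23S, animal 136).

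The splicing factors had calls in 4 of 8 background members, against 2.59 expected. Besides Zrsr2 these were Prpf8 (P436T) and Srsf1 (E120*, a premature stop on chromosome 11 at 88048653) in animal 54, and Sf3a3 (G276E) in animal 136. Chromatin and DNA methylation regulators had calls in 10 of 23, against 7.45 expected, and besides Dnmt3a and Kmt2a these were Kmt2c (C4232F), Setd1b (S214R) and Dnmt1 (D772G) in animal 54, Tet1 in animals 108 (V144L) and 136 (E797G), and Dnmt3b (V180I), Arid1a (D1026G and Q544H), Arid2 (A524S and L1447I) and Kdm5c (G1109D) in animal 136. This list had 10 genes against 3.43 expected with genes having any call as the background (exact adjusted p = 0.0123), 10 against 3.46 with RefSeq coding genes (exact adjusted p = 0.0131), and 6 against 3.06 with genes of the all-variant lists (exact adjusted p = 0.622), so its call depended on the background.

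The p53 pathway and DNA repair list had calls in 6 of 20, against 6.48 expected. Mutyh (K126N), Pold1 (L620P) and Prkdc (K3734N) were hit in animal 54, the mismatch repair genes Pms2 (D854Y) in animal 108 and Msh6 in animals 108 (D931Y) and 136 (L871I), and Atm (C2624F) in animal 136. Haematopoietic transcription factors had calls in 4 of 14, against 4.54 expected, which besides Etv6 were Mecom (R781H, animal 54), Erg (P122S, animal 108) and Hoxa9 (A46S, animal 136). Besides Smc3 the cohesin list had Rad21 (E490G, animal 108), giving 2 of 8 against 2.59 expected. None of 13 background members of the RAS and cytokine receptor signalling list had a call, against 4.21 expected. Antigen receptor segments had calls in 20 of 139 genes, 15 by VarScan2 and 5 by Strelka, against 45.0 expected. The multigene families prone to ambiguous alignment had calls in 91 of 386 genes, 26 by VarScan2 and 65 by Strelka, against 125 expected. These expected numbers pool both callers and follow mostly from Strelka. It had 1115, 608 and 826 genes with a protein-altering call in animals 54, 108 and 136, against 51, 53 and 16 for VarScan2. A shortfall or excess of VarScan2 calls in these families can therefore not be read from them, and was not tested.

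The base changes of the Strelka calls were led by C to A, and those of VarScan2 were closer to inherited variation. C to A made up 42.2%, 40.5% and 40.8% of the Strelka single nucleotide calls of animals 54, 108 and 136, 17.2%, 13.5% and 17.4% of those of VarScan2, and 9.38%, 9.02% and 12.1% of the sites shared by both tissues. C to T, the change that spontaneous deamination of methylated cytosine gives, made up 32.1%, 32.5% and 31.1% of the Strelka calls and 31.8%, 33.4% and 28.1% of shared sites. All 6 classes together differed from the shared sites for Strelka in each animal (chi-square permutation test, 100000 resamples, p = 1e-05, the smallest they can give). For VarScan2 the same permutation test gave p = 1e-05 in animals 54 and 108 and p = 0.00198 in animal 136.

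**Figure D4:**
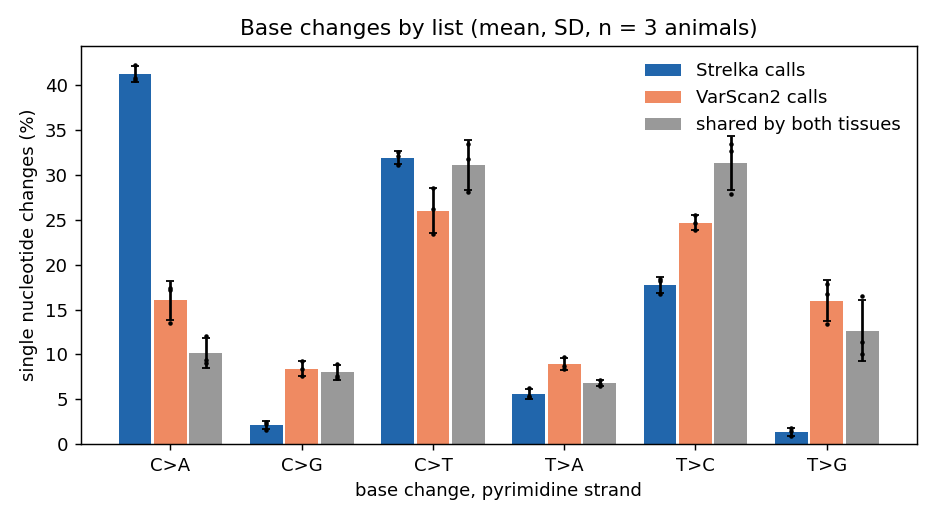
Percent of single nucleotide changes in each of 6 pyrimidine-based classes (x axis) for Strelka calls, VarScan2 calls and sites shared by both tissues. Bars are means with SD over 3 animals and points are animals, and the C to A bar of Strelka, between 40.5% and 42.2% in the animals, stands above the other lists.

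Few sites passed the test for a difference in allele fraction between marrow and ear of the same animal. Of 31835 sites tested in animal 54, 11 passed an adjusted p of 0.05 (two-sided Fisher exact test per site, Benjamini-Hochberg), 3 higher and 8 lower in marrow. In animal 108 it was 16 of 48977 sites, 10 higher and 6 lower in marrow. In animal 136 it was 2 of 11026, both higher in marrow. Some of these sites lay close together, at Myo3a in animal 54 and at Sorl1, Fsip1 and Sfi1 in animal 108. The counts are therefore of sites and not of separate loci. At an unadjusted exact p under 0.05 there were 2678, 3638 and 686 sites, 8.41%, 7.43% and 6.22% of those tested, where simulated sites with no difference gave 3.26% to 3.91%. Of the 29 sites past the threshold 2 changed a protein, and these, outside the rule for named genes and picked after their values were seen, were an in-frame deletion in the leiomodin gene Lmod1 in animal 54 (67.1% in marrow, 31.5% in ear) and p.Ile493Val in the contactin gene Cntn4 in animal 136 (59.6% and 14.9%).

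Over the 3 animals, 4444 sites called in all 6 samples were tested with animal as the stratum (Cochran-Mantel-Haenszel test, two-sided, Benjamini-Hochberg), and 1 passed, against 358 (8.06%) at an unadjusted p under 0.05, where simulated sites with no difference gave 3.61% to 4.29%. An exact conditional test over the same strata, added after the data were seen, also gave 1 site, and its p-values are given here. The site that passed lay in an intron of Sfi1, a centrin-binding spindle protein gene, on chromosome 11 at position 3132878. Its variant fraction in marrow and ear was 98.2% and 96.3% in animal 54, 98.2% and 96.9% in animal 108, and 98.7% and 96.3% in animal 136, a mean difference of 1.81 points ± 0.566 (SD, n = 3; exact adjusted p = 0.00417), at a mapping quality of 20. Other Sfi1 sites that passed the test within 1 animal were lower in marrow. They were position 3153284 in animal 54 (-4.64 points) and 3188669 and 3188670 in animal 108 (-15.5 and -14.2 points). Among sites that moved the same way in all 3 animals, missense changes in Zfp180 and Hdhd5 came next. In the zinc finger gene Zfp180 (p.Arg225Cys, chromosome 7 at 24104830) the mean difference was -21.1 points ± 14.2 (SD, n = 3). In Hdhd5 (p.Arg33Gln, chromosome 6 at 120531195) it was -28.1 points ± 2.33 (SD, n = 3). Both changes were lower in marrow in 3 of 3 animals, a shared direction that the naming rule requires, and missed the threshold (exact adjusted p = 0.0549 for each). The other named sites, in Lrp1b, C230088H06Rik, Ugt1a1, Spata20, Cntn4 and Tmem72 and between A2m and Mug1, had exact adjusted p between 0.112 and 0.172. Of the 10 named sites 7 had the lower fraction in marrow. By the Cochran-Mantel-Haenszel test 12 sites passed without animal 54, 9 without animal 108 and 5 without animal 136, where more sites could be tested (8442, 5231 and 6617).

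The genes altered in more than 1 animal differed between callers. By VarScan2 10 genes had protein-altering calls in at least 2 animals, 3 of them in all 3, against 0.581 ± 0.756 (SD) expected from 10000 random draws from the 7506 background genes (a one-sided permutation of gene labels, p = 0.0001, the smallest these draws can give). Without animal 54 it was 4 genes, without animal 108 it was 5 and without animal 136 it was 7. Without the multigene families 4 of the 10 were left, against 0.297 expected. Identical VarScan2 calls were present in 2 animals 7, 11 and 21 times for the pairs 54 with 108, 54 with 136, and 108 with 136. Strelka had no identical call in any pair of animals, and 200 genes with protein-altering calls in at least 2 animals against 260 ± 12.8 (SD) in draws from the same background, which its own calls make up in part. The direction depended on the draws. Against all RefSeq coding genes, chosen after the data were seen, 199 genes stood against 90.6 ± 8.62 (SD) expected (one-sided permutation of gene labels, p = 0.0005, the smallest 2000 draws can give). With draws weighted by coding length, again from the background of called genes alone, 200 stood against 420 ± 13.3 (SD). The 10 genes hit in all 3 animals by Strelka, named after their values were seen, were Birc6, Dnmt3a, Dock6, Fbn2, Hmcn2, Pkd1l2, Ppp1r21, Syne2, Ticrr and Tpx2.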

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

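Of the tests in this part, those on calls with a clean ear, on low ear counts, on C to A shares and on the neighbourhood of Srsf2 were chosen after the results were seen, as was the limit of 50 shared sites per Mb that defines a site-rich window.

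Calls in data outside the main comparisons were those that VarScan2 marked LOH, 253 in animal 54, 183 in animal 108 and 64 in animal 136. They are listed because no main comparison used them, although an alternative count of VarScan2 calls took them in. No control list shows how many such calls arise without a loss. The median variant fraction of these calls was 80.7% in marrow and 40.7% in ear of animal 54, 80.04% and 40% in animal 108, and 83.0% and 50.6% in animal 136, and 2 of the 500 calls had the lower fraction in marrow. Median depth at them was 13, 19 and 22 reads in marrow.

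The first pattern is that the callers shared 11 calls. The tables argue against a clean ear being the whole difference, because Strelka listed 10 of the 575 VarScan2 single nucleotide calls with no variant read in ear (1.74%, 95% Clopper-Pearson interval 0.837 to 3.18). They also argue against heterozygous sites under-sampled in ear as the source of most calls in site-rich windows of animals 54 and 136. In windows rich in sites shared by both tissues lay 40.7% of VarScan2 single nucleotide calls, against 7.14% for Strelka (a ratio of 5.69). Of these 1096 calls, 726 (66.2%) had an ear count too low for a heterozygous site (exact one-sided binomial p under 0.0001). Sampling gives 8.45 such counts among all shared sites. By animal the share was 89.2%, 51.0% and 72.4% in animals 54, 108 and 136. In animal 108 it held for 310 of 608 calls, so under-sampling stays open for the rest there. Median depth in ear and marrow was 106 and 41 reads in animal 54, 23 and 34 in animal 108, and 37 and 41.5 in animal 136. What the calls are stays open; of all VarScan2 single nucleotide calls, 64.9%, 70.4% and 70.4% in animals 54, 108 and 136 had their marrow variant reads on 1 strand, and 15.9%, 28.1% and 35.6% were in all-variant lists of other animals, against 0 to 0.270% for Strelka. No biological explanation was tested for the difference between callers.

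The second pattern is the lead of C to A in the Strelka calls. A change made in the libraries of both tissues is a candidate explanation, since ear-private coding sites at under 20% variant reads had C to A shares of 25.8%, 38.6% and 30% in animals 54, 108 and 136, at least 2.65 times those of shared coding sites. These ear shares argue against a mutation process of marrow alone as the only source of C to A at such low-fraction sites, since it would give no such excess in ear. They cover low-fraction tissue-private sites and not the Strelka calls themselves, so the source of C to A in the Strelka calls stays open. A part added in marrow cannot be told apart, since marrow-private sites had the higher share in 2 of the 3 animals (38.1%, 32.9% and 32.8%). That difference passed Fisher's exact test in animal 54 (p = 0.000191) and not in animals 108 (p = 0.0816) and 136 (p = 0.380).

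The last pattern is the lower Srsf2 codon 95 share in marrow of animal 108. The tables argue against a change of the whole 5 Mb on each side, which would move sites on either parental copy: the median size of the marrow minus ear difference in fraction, sign left out, was 0.0747 at 80 heterozygous sites there (95% bootstrap interval 0.0479 to 0.0852), with 0.0604 from sampling alone. A change of a shorter segment stays open. Variation between sites remains possible: of 8151 heterozygous sites of this animal at 40 to 80 reads in both tissues, 309 (3.79%) had an exact p as small, and this share times 3 animals is 0.114. A smaller share of marrow cells carrying the change in this animal stays open and was not tested.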

How the results depend on the processing

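Of the tests in this part, the adjacent base of Srsf2, the ear-private background, the RefSeq and all-variant backgrounds of the lists, the mean Srsf2 difference, the exact conditional test and those with LOH calls, mapping quality, coding length or RefSeq genes were chosen after the results were seen. Of the alternatives, 85 kept direction and side of the threshold, or, for numbers of calls, sites, genes or lists, moved by at most 1.5 times. Another 23 numbers moved further, 2 alternatives lost the threshold and 4 turned the direction. Part of the 85 could not have changed. Every sample already had at least 20 reads at the Srsf2 codon, and no VarScan2 single nucleotide call lay under the 10% marrow limit. The paired tests over animals cannot go below 0.25 with 3 pairs, so their side of the threshold was fixed. The ear-private background gave an odds ratio of 0.719 for protein-altering VarScan2 calls, and genes of the all-variant lists as background one of 0.379 for the myeloid list. Leaving out 1 animal moved the mean log2 ratio of sites between -0.28 and 0.17 and of tissue-private sites between -0.78 and 0.48, both positive without animal 54. The Srsf2 difference of animal 108 was -18.3 points at the adjacent base (exact adjusted p = 0.123), and the C to A excess was 17.8 points in calls by both callers (exact p = 0.0796), of which there were 11. The cause of these changes was not tested, apart from the fewer calls and animals.

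Stricter thresholds left means of 316 VarScan2 and 688 Strelka single nucleotide calls and 51.7 VarScan2 indels per animal, and a depth of at least 20 reads left 546 and 104 VarScan2 calls of each kind and 3 calls by both callers. With genes having any call, or RefSeq coding genes, as background, 1 list passed. Sites that differed in animal 54 numbered 17 and 19 at depths of at least 20 and 30, those in animal 136 numbered 5 at 30, and Bonferroni left 3, 5 and 1 in animals 54, 108 and 136. Genes in more than 1 animal numbered 200 by Strelka, 0 by both callers, 4 without multigene families, and 4 to 7 with 1 animal left out.

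Without the replicate block that pairs the tissues, 8 sites differed over 3 animals on summed reads, against 1 with pairing, and 5 to 12 with pairing and 1 animal left out. Without pairing the Srsf2 mean difference stayed at -9.40 points (exact permutation p = 0.6), with -17.1 to -3.59 when 1 animal was left out, and the log2 ratios at -0.10 and -0.26 (exact permutation p = 1 and 0.6), tests that cannot go below 0.1 with 3 samples a group.

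Not run were a variant quality of at least 100, which the lists do not hold, Srsf2 reads from a somatic list, since none holds it, and depth or fraction limits for Strelka, which has no reads. Protein-altering calls by both callers gave no finite odds ratio. On simulated shifts of 0.2 the Fisher step recovered 16.5%, 12.5% and 17% of changed sites in animals 54, 108 and 136, so depth limits shifts of that size.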

Other observations

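The tests in this part on Rosa26, on Dnmt3a, on differences by chromosome and on swapped tissues were chosen after the results were seen, and so were the bounds that decided those on Rosa26 and Dnmt3a. In the site-rich windows the median variant fraction was 47.4% in marrow and 47.4% in ear of animal 54, 47.5% and 47.6% in animal 108, and 48.3% and 48.6% in animal 136.

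In the same windows, the size of the marrow minus ear difference in fraction was averaged with its sign left out, since the sites were not assigned to a parental copy. Over 29 pairs of animal and chromosome with at least 100 heterozygous sites there (12 in animal 54, 13 in animal 108 and 4 in animal 136), this mean lay between 4.64 and 9.57 percentage points, 1.11 to 1.27 times that from read sampling alone. Chromosome parts outside these windows, and sites that one tissue lacked, were not covered.

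Of 17 windows rich in shared sites in all 3 animals, 9 lay on chromosome 6 within 10 Mb of the Rosa26 locus (Gt(ROSA)26Sor, chromosome 6, 113067428 to 113077244). The R26-CreERT2 driver and the R26eYFP reporter named in the labels and design text sit at Rosa26, and the hypothesis that a haplotype was inherited with this locus came from these same windows. Neighbouring windows are not independent, and with those under 10 Mb apart joined there were 7 stretches, of which 1 (14.3%, 95% Clopper-Pearson interval 0.361 to 57.9) was near Rosa26, too few to decide. The median mapping quality of sites in the 9 windows was 42, against 36 in the other 8, and the window of the locus itself held 1, 1 and 0 shared sites in animals 54, 108 and 136.

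Dnmt3a stood first among 6385 genes when the number of protein-altering Strelka calls was set against coding length. It had 5 such calls against 0.501 expected (exact Poisson p = 0.000174), and 0 synonymous calls. These 6385 genes are fewer than the 21900 RefSeq coding genes. A wider set would lower the expected number, so that number and the p-values depend on the set. The hypothesis that Dnmt3a was hit beyond chance had an exact p of 0.0316 adjusted over the list alone (182 genes) and of 1 adjusted over all genes, so chance cannot be told apart from it on these calls. None of the 5 calls was in the marrow list of all variants, and in the authors' deposited table their Strelka qualities were 24, 43, 76, 18 and 16 in the order H584N, L633Q, R362H, A42S and A382T.

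The test over 3 animals had 1 site past the threshold, and the other 3 ways of swapping tissues within animals gave 6 to 21, so the real arrangement had the fewest. With reads summed over animals the real split gave 8 sites and the highest of the other splits 278. Neither 4 swaps nor 10 splits can give a share under 0.05. Splits that set the tissues of all 3 animals apart gave 8 to 39 sites, the real one included, and those that set apart the tissues of 1 animal gave 110 to 278, which points to differences between animals.

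A mitochondrial change at position 4891 in mt-Nd2, synonymous, was nearly fixed in both tissues of animal 136 (7751 of 7766 reads in marrow, 7782 of 7796 in ear) and was not called in the other 2 animals. The lists of animal 136, a female per the labels, held 26 chromosome Y sites in marrow and 29 in ear, at a median mapping quality of 8 and 9, against 26 to 31 in the samples of both males.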
